A study of Mus musculus with 6 samples.

How the data were processed

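Total RNA from microdissected tibial growth plates of 6 samples was amplified and labelled as cDNA before hybridisation to an Agilent mouse oligonucleotide array, per the labels' protocols. The labels give Cy5 as the dye of every sample. The deposited scanner files hold intensity values per spot, made with Agilent Feature Extraction 10.7.1.1 per the submitters' processing notes. Per the file headers, the knockout arrays were extracted with a 2-channel protocol set for Cy5 only, and the WT arrays with a 1-channel protocol whose channel is named green. For the knockouts the red channel was therefore used, and for WT the only channel. The deposited files give the median intensity of each spot and the median background intensity around it, and these medians were used where the design had named the mean spot intensity. The authors' value table of the same arrays holds log2 values, which was determined by setting each column against the scanner signals. Between arrays, the differences in the authors' log2 table followed the green processed signal, with r of at least 0.9987 and a slope close to 1, including in the knockout columns, where the labelled red channel gave r of 0.0392 to 0.067 within the slide. The values differ from that signal by a constant per array and a constant per probe, and how these constants were chosen stays unknown; the column medians were 0.2 and 0.1 for ATF6aKO, 0 and 0.221 for ATF6bKO, and -0.5 and -0.5 for WT. That table served only as an alternative.

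Each array had 62976 spots, of which 59305 were not controls and represented 55681 probes. The median spot intensity was 183 and 165 in ATF6aKO, 162 and 146 in ATF6bKO, and 260 and 210 in WT, over a median background of 37 on the knockout arrays and 17 on the WT arrays. Spots well above background made up 91.4% and 91.7% in ATF6aKO, 90.3% and 86.9% in ATF6bKO, and 96.7% and 90.3% in WT. Spots marked as outliers numbered between 125 and 177 on 5 arrays and 574 on WT replicate 2. The median coefficient of variation of repeated spots lay between 7.42% and 11.9% on those 5 arrays and at 17.3% on WT replicate 2.

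Background was corrected with normexp (limma 3.58.1 in R 4.3.3, offset 50), values were taken to log2, control and outlier spots were left out (288 probes were left out for such flags), spots of a probe were averaged, and arrays were quantile normalised. The scanner files identify probes by accession, and RefSeq accessions were matched to symbols through a gene table of assembly GRCm38.p6, used for names only. Of the probes, 26582 matched 20145 symbols. The other 29099 probes, among them 16194 that stand for genomic intervals, were not analysed here except in an alternative. No coordinates are given, because the array design and the gene table use different builds. A probe was kept if it was well above background on both arrays of at least 1 genotype, and the brightest kept probe stood for its gene, which left 19122 genes. Where a second probe existed (4859 genes), both were called in 1037 genes for ATF6aKO against WT, in opposite directions in 293 of them. For ATF6bKO against WT both were called in 795 genes, in opposite directions in 225 of them. Across the 4859 genes the log2 differences of the 2 probes correlated at r = 0.284 for ATF6aKO and 0.247 for ATF6bKO against WT.

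The 3 comparisons were fitted together over the 6 arrays with lmFit and eBayes, with a threshold of 0.05 on the Benjamini-Hochberg adjusted p. Leaving out an array leaves a genotype with 1, which is then assumed to vary like the others. For a gene not well above background on any array of a genotype, the fold is a bound, taken from the other genotype's mean against the higher of the gene's own signal and the lowest signal well above background on each array. For most of the genes named, this bound equals the measured fold. Gene lists (26, of which 12 are for the growth plate and ER, 10 for other cell types and 4 general) were tested with camera at a preset correlation of 0.01, and again with an estimated one. The lists, the rule for naming genes and the alternatives were fixed before the data were examined, unless stated otherwise. The rule named Atf6 and Atf6b; in each comparison the 5 largest rises and falls past the threshold whose arrays did not overlap, with 3 bounds each way, or, where no gene passed, the 5 of smallest p each way; and the members of smallest p in each list, with the most expressed marker of each other cell type. Clone-like symbols were passed over. Which of the list members to print and which only to count was chosen after the values and alternatives were seen, and Hspa5 and Xbp1 lie outside the rule.

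The procedure was tested on simulated data in which 200 of 19122 genes were changed by known amounts. For ATF6aKO against ATF6bKO it recovered 25.8%, 92.0% and 99.5% of genes changed by 1, 2 and 4 log2 units. For ATF6aKO against WT the shares were 33.8%, 94.5% and 100%, and for ATF6bKO against WT 25.8%, 94.5% and 99.5%. The simulated data held few changed genes, no channel effect and the same spread of a gene on every array. Against WT, 42.7% of genes passed in ATF6aKO and 37.6% in ATF6bKO, with log2 differences down to 0.442 and 0.455. The shares recovered therefore do not describe the comparisons with WT. Alternatives covered the signal column, 75th percentile scaling, the authors' table, the filter on dim probes, the mean over probes, fitting only the arrays compared, a trended and robust variance, a block for the replicate number, leaving out each array, a log2 difference over 1 and the estimated correlation. Testing all features and a crossed replicate block were added after the data were examined.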

Results

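The series measured gene expression in the growth plate, the cartilage layer through which long bones lengthen, of male C57BL/6J mice aged 4 weeks. Tissue was taken from the tibia by laser microdissection. There were 3 genotypes with 2 arrays each, namely mice labelled as knockouts of ATF6a (gene Atf6), knockouts of ATF6b (gene Atf6b) and wild type (WT). ATF6a and ATF6b are transcription factors that sit in the membrane of the endoplasmic reticulum (ER) and are released by cleavage when unfolded proteins build up there. The title states the question, which is the role of this ER stress transducer in long bone growth. The labels do not say whether the 2 arrays of a genotype came from separate animals. The limma p-values below therefore measure only the spread between arrays, which may be technical. The camera and permutation p-values set genes against other genes, and they do not measure the spread between animals either. Between 86.9% and 96.7% of non-control spots lay well above background, and the small number of arrays limits the precision of every value. Probes for 19122 named genes entered the tests.

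The 4 knockout arrays were scanned together on 1 slide with 2 channels, and the 2 WT arrays on another slide with 1 channel. Batch and group cannot be told apart in either comparison with WT, because no slide held both WT and knockout arrays. Only ATF6aKO against ATF6bKO was made within a slide, and there each genotype filled its own slide row. Across probes, knockout arrays correlated with one another at r between 0.9704 and 0.9881, whereas knockout and WT arrays correlated at r between 0.8508 and 0.9057. The 2 WT arrays correlated at r = 0.96.

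The targeted genes come first because they bear on the labels. Atf6 measured 7.02 ± 0.07 (normalised log2 intensity, SD, n = 2) in ATF6aKO, 6.96 ± 0.07 in ATF6bKO and 7.17 ± 0.17 in WT. The log2 difference between ATF6aKO and WT was -0.15 ± 0.17 (SE; limma adjusted p = 0.498), which was within the replicate spread. Atf6b measured 8.70 ± 0.31 in ATF6aKO, 8.59 ± 0.25 in ATF6bKO and 9.13 ± 0.10 in WT. Its log2 difference between ATF6bKO and WT was -0.54 ± 0.21 (SE; limma adjusted p = 0.0824), not past the threshold. Each gene had 1 kept probe matched by RefSeq accession, while 29099 probes of the array were not matched to any gene. The labels do not locate the deleted part, so these probes check nothing certain about the genotypes. Under 75th percentile scaling the Atf6 difference between ATF6aKO and WT was 0.08, and in the authors' deposited table it was 0.95, while Atf6b in ATF6bKO lay at -2.15 from WT there. The knockout columns of that table follow the green channel, in which 54.4% to 59.2% of probes on the knockout arrays and 0% on the WT arrays had a processed signal of 1 or less, so its differences from WT carry that contrast.

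**Figure D1:**
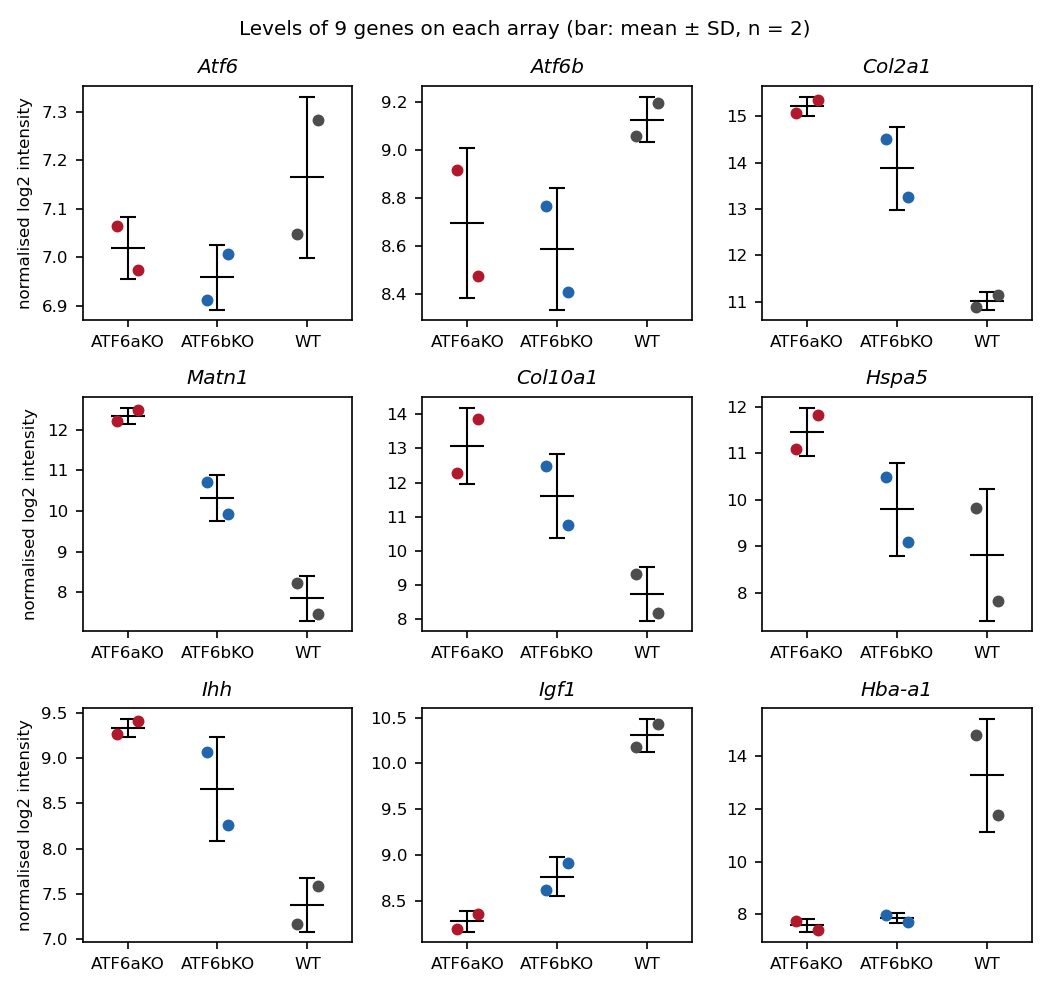
Normalised log2 intensity (y axis) of 9 genes in ATF6aKO, ATF6bKO and WT (x axis), with 1 point per array and bars for the mean ± SD (n = 2); each panel has its own y range. Col2a1 averaged 15.2 in ATF6aKO, 13.9 in ATF6bKO and 11.0 in WT, whereas Atf6 stayed between 6.96 and 7.17 in all 3 genotypes.

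ATF6aKO against WT asked what differs in the growth plate without ATF6a. Of 26 cartilage matrix and chondrocyte regulator genes 19 rose in ATF6aKO and 3 fell, and the list passed with a preset correlation (camera adjusted p = 1.37e-05) but not with an estimated one (adjusted p = 0.879). Matn1, encoding the cartilage matrix protein matrilin-1, was 22.5-fold higher (log2 difference 4.49 ± 0.33, SE, n = 2 per genotype; limma adjusted p = 0.000463). Col10a1, the collagen of hypertrophic chondrocytes, was 20.3-fold higher, and Col2a1, the main fibrillar collagen of cartilage, 18.3-fold higher. Cdkn1c, a cyclin-dependent kinase inhibitor, rose 14.4-fold and Col11a1, another fibrillar cartilage collagen, 13.3-fold. The largest falls were in Hba-a1, an alpha-globin gene of red cells, at 52.3-fold, Eef2, the translation elongation factor, at 10.6-fold, Grm8, a glutamate receptor gene, at 8.24-fold, Il34, a cytokine of the macrophage lineage, at 7.95-fold, and H2-Q2, an MHC class I gene, at 7.61-fold. The adjusted p of these 10 genes lay between 0.000463 and 0.00493. Single arrays moved some of these folds widely. Hba-a1 (WT 13.3 ± 2.15, SD, n = 2) was 18.2-fold lower without WT replicate 1 and 150-fold lower without WT replicate 2, and H2-Q2 3.79-fold and 15.3-fold lower. Without ATF6aKO replicate 1 or replicate 2, Col10a1 was 35.1-fold or 11.8-fold and Cdkn1c 21.9-fold or 9.49-fold higher. In the authors' deposited table the log2 difference of Matn1 was 0.001, H2-Q2 did not pass, and Col10a1, Col2a1, Cdkn1c and Eef2 had the opposite sign.

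In total 8157 of 19122 genes (42.7%) passed the threshold in ATF6aKO against WT, 3886 higher and 4271 lower. Of these, 3593 also differed by over 2-fold. The counts within lists stand beside that share of 42.7%. With 75th percentile scaling the split was 5163 higher and 3601 lower, after a shift of the median of all genes from -0.027 to 0.132 on the log2 scale. With the authors' deposited values it was 6893 higher and 2824 lower, after a shift to 0.85. Without ATF6aKO replicate 2 the count was 4682. Some genes were not well above background on any array of a genotype and are given as bounds. These bounds, here and below, allow for the dim signal but not for the spread between arrays or probes. Sox9, the master transcription factor of chondrocytes, was at least 3.26-fold higher in ATF6aKO, Nlgn3 at least 2.71-fold and the olfactory receptor gene Olfr77 at least 2.34-fold. Trp53i11 was at least 4.77-fold lower, Trp53rkb at least 4.34-fold and Myo10 at least 3.43-fold; Nlgn3 did not pass when the probes of a gene were averaged, and Myo10 did not pass without either ATF6aKO array or with a trended and robust variance. The log2 difference of Myo10 was -0.89 without WT replicate 1 and -2.67 without WT replicate 2. With the processed signal these 6 genes lay further from WT, from 3.30 for Olfr77 to 6.08 for Nlgn3 and from -4.34 for Trp53rkb to -3.81 for Myo10. Genes well above background on both arrays of 1 genotype and on neither array of the other numbered 86 for ATF6aKO and 471 for WT. Genes whose bound ran the other way were not counted. Detection was in different channels, with a median background of 37 on the knockout arrays and 17 on the WT arrays. Between the knockouts, on 1 slide, the numbers were 256 for ATF6aKO and 22 for ATF6bKO. Detection differed there as well, with 91.4% and 91.7% of spots well above background in ATF6aKO and 90.3% and 86.9% in ATF6bKO.

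Of the cartilage matrix and chondrocyte regulator list, 19 of 26 measured members rose in ATF6aKO, 3 fell and 4 did not pass (adjusted over the list alone, 19 and 4). Their median log2 difference was 2.0, whereas it was -0.41 in the authors' deposited table, whose knockout columns follow another channel. The camera test with its preset correlation gave an adjusted p of 1.37e-05, and the adjusted p was 0.879 with an estimated correlation. Of 29 ER chaperones and folding enzymes, 8 rose and 1 fell, both over all genes tested and adjusted over the list alone. Fkbp11, a prolyl isomerase, rose 6.10-fold and Ero1a, the oxidase that renews protein disulfide isomerase, 3.91-fold. Hspa5, the chaperone BiP and a textbook target of ATF6, was named after its values were seen. It was 2.64 ± 0.68 higher on the log2 scale (SE; limma adjusted p = 0.0171), and it did not pass without either ATF6aKO array or with a trended and robust variance. The WT arrays moved it too, to 3.64 without WT replicate 1 and 1.64 without WT replicate 2. The chaperone list passed with an adjusted p of 0.0488, against an adjusted p of 0.879 with an estimated correlation. Its median was 0.31, or 0.55 without WT replicate 1 and 0.48 without ATF6aKO replicate 1; it did not pass without WT replicate 2 (median 0.14, adjusted p = 0.205) or without ATF6aKO replicate 2 (median 0.23, adjusted p = 0.134). Nor did it pass with the processed signal (adjusted p = 0.101), with the mean over probes (adjusted p = 0.054) or with probes well above background on all 6 arrays (adjusted p = 0.0598). Of 53 genes for the translocon, COPI and COPII coats and glycosylation, 20 rose and 7 fell (adjusted over the list alone, 22 and 8), with a list adjusted p of 0.0271, and 0.879 as the adjusted p with an estimated correlation. Tmed10, a cargo receptor of the early secretory pathway, rose 5.13-fold and Cope, a COPI subunit, fell 2.49-fold. That list had a median of 0.63, or 1.08 without WT replicate 1, and no longer passed with probes well above background on all 6 arrays (adjusted p = 0.0598), without WT replicate 2 (median 0.18, adjusted p = 0.386) or without ATF6aKO replicate 2 (median 0.51, adjusted p = 0.146). With 75th percentile scaling the cartilage list was the only 1 of the 5 lists past the threshold that still passed, and the adjusted p was 0.112 for chaperones and 0.115 for the translocon list. In the authors' deposited table both of these lists had a median of 3.5. With the mean over probes, the log2 difference of Tmed10 was 1.0 instead of 2.36.

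None of the remaining growth plate lists passed, and all but the resting zone list had members past the threshold in both directions. In the resting zone list 0 of 9 members had a positive log2 difference, with a median of -0.67. Its camera adjusted p was 0.07 with the preset correlation and 0.879 with an estimated one. Adjusted over the list alone, the counts of these lists were within 1 of those given, except that 6 of the PERK and ATF4 stress genes fell. Of 13 ER stress sensors and relatives of ATF6, 3 rose and 2 fell. Creb3l1, the ATF6 relative also called OASIS, fell 3.01-fold, and Eif2ak3, the sensor kinase PERK, was at least 1.94-fold higher because it was not well above background in WT. Xbp1, the transcription factor activated by IRE1 and also named after its values were seen, rose by a log2 difference of 2.01 ± 0.40 (SE; limma adjusted p = 0.00671) but did not pass without ATF6aKO replicate 2. Of 29 PERK and ATF4 stress genes, 1 rose and 10 fell; Atf4 itself rose 3.49-fold and Ddit3, encoding CHOP, fell 2.61-fold. Of 17 hypertrophic chondrocyte genes, 6 rose and 3 fell, and Ihh, the growth plate's hedgehog ligand, rose 3.87-fold while the transglutaminase gene Tgm2 fell 2.23-fold. Of 32 growth plate signalling genes, 11 rose and 6 fell, with Bmpr1b, a BMP receptor gene, 2.45-fold higher and Igf1, the growth factor downstream of growth hormone, 4.07-fold lower; that list's median was -0.09 and its mean 0.12. Of 9 resting zone genes, 4 fell and 0 rose, among them Apoe at 2.80-fold and Barx1 at 2.40-fold. Of 27 cell cycle genes, 11 rose and 3 fell, with the survivin gene Birc5 4.10-fold and the replication licensing gene Mcm2 2.03-fold higher. Of 28 collagen modification genes, 6 rose and 6 fell, and P3h4, of the prolyl 3-hydroxylase family, and Fkbp10, a prolyl isomerase that acts on collagen, were 9.49-fold and 8.64-fold higher. Of 26 hypoxia and glycolysis genes, 9 rose and 6 fell, with Ldha 8.64-fold higher and the phosphofructokinase gene Pfkl 4.24-fold lower. Of 18 genes for ER-associated degradation, 3 rose and 4 fell, and Herpud1 and Ube2j1 were 2.24-fold and 2.10-fold higher. With the mean over probes the log2 differences were smaller for Ldha (0.64 instead of 3.11), Igf1 (-0.70 instead of -2.02), Birc5 (0.79 instead of 2.04), Bmpr1b (0.58 instead of 1.29) and Tgm2 (-0.51 instead of -1.15).

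Some markers of other cell types passed the threshold too, beside 42.7% of all genes tested. Of 17 endothelial markers, 8 fell and 0 rose, with Plvap 3.39-fold and the VEGF receptor gene Kdr 2.37-fold lower. That list had a median of -0.59 and an adjusted p of 0.0271, and the adjusted p was 0.879 with an estimated correlation. It did not pass without WT replicate 1 (adjusted p = 0.0707) or without ATF6aKO replicate 2 (adjusted p = 0.0693), nor with 75th percentile scaling (adjusted p = 0.0524), with probes well above background on all 6 arrays (adjusted p = 0.0598) or with the authors' deposited values (adjusted p = 0.338), and its median was -0.93 with the processed signal. No other marker list passed. Among osteoblast and osteocyte markers 4 of 12 fell, among osteoclast markers 2 of 14 rose and 3 fell, among erythroid markers 3 of 13 rose and 4 fell, and among macrophage markers 1 of 15 rose and 7 fell. The osteocalcin gene Bglap2 was 3.44-fold lower and the red cell anion exchanger gene Slc4a1 5.0-fold lower, while the lysozyme gene Lyz2 was 5.11-fold higher. Among neutrophil markers 2 of 17 rose and 4 fell, among B cell markers 2 of 13 rose and 3 fell, among skeletal muscle markers 2 of 18 rose and 5 fell, among adipocyte markers 4 of 14 fell, and among perichondrium, tendon and synovium markers 1 of 13 rose and 2 fell. Tnni2, a fast muscle troponin gene, was 8.49-fold higher, or 14.7-fold without WT replicate 1 and 4.92-fold without WT replicate 2. The osteoblast and osteocyte list stood high on 1 WT array only, with a median deviation from the mean over the 6 arrays of 1.22 on WT replicate 1 and -0.28 on WT replicate 2, against -0.43 to -0.20 on the knockout arrays, and the osteoclast list stood at 0.37 and -0.13 on the WT arrays. Col1a2, the type I collagen gene of bone, differed between the 2 WT arrays by far more than between genotypes (WT 12.3 ± 5.23, SD, n = 2), and its log2 difference from WT was 2.65 without WT replicate 1 and -4.75 without WT replicate 2. Of 29 ribosomal protein genes, 16 rose and 3 fell (median 0.76, list adjusted p = 0.00767, with an adjusted p of 0.879 with an estimated correlation and of 0.0911 under 75th percentile scaling), with Rps24 6.98-fold higher; the median was 1.47 without WT replicate 1, 0.51 without WT replicate 2 and 5.35 in the authors' deposited table, and the log2 difference of Rps24 was 1.51 with the mean over probes instead of 2.8. Oxidative phosphorylation genes rose in 10 and fell in 4 of 32, immediate early and heat shock genes rose in 4 and fell in 6 of 20, and interferon response genes rose in 4 and fell in 3 of 18; these lists did not pass. Medians and means differed in sign for the lists of ER-associated degradation (-0.01 and 0.04) and of the interferon response (-0.01 and 0.03).

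ATF6bKO against WT put the same question for ATF6b. Col2a1 was 7.26-fold (log2 difference 2.86 ± 0.37, SE, n = 2 per genotype; limma adjusted p = 0.00177) and Matn1 5.52-fold above WT. Without ATF6bKO replicate 1 or replicate 2, Col2a1 was 4.69-fold or 11.2-fold higher. The largest rises were in Olfr1386, an olfactory receptor gene, at 12.7-fold, D7Ertd143e at 11.4-fold, Smim13 at 9.74-fold, Fbxw7, a ubiquitin ligase subunit gene, at 9.51-fold, and Rmrp, the RNA of the ribonuclease MRP, at 8.80-fold. The largest falls were in Hba-a1 at 43.4-fold, Eef2 at 12.5-fold, the ubiquitin gene Ubb at 10.2-fold, Adgrb2, an adhesion receptor gene, at 9.09-fold and Il34 at 8.40-fold. Their adjusted p lay between 0.000534 and 0.0315. The WT arrays differed in several of these genes, with an SD of 1.98 for Olfr1386, 2.76 for D7Ertd143e and 2.15 for Hba-a1. Without WT replicate 1 or replicate 2, Olfr1386 was 33.5-fold or 4.82-fold, D7Ertd143e 44.0-fold or 2.94-fold and Smim13 15.4-fold or 6.17-fold higher, and Hba-a1 was 15.1-fold or 124-fold and Ubb 5.21-fold or 20-fold lower. D7Ertd143e did not pass without any 1 of the 4 knockout arrays or with only the 4 arrays compared, and neither D7Ertd143e nor Olfr1386 passed with a trended and robust variance. In the authors' deposited table none of the 5 rises passed, and Col2a1, Matn1, Eef2 and Ubb had the opposite sign. With the mean over probes the log2 differences were smaller for D7Ertd143e (1.72 instead of 3.51), Fbxw7 (2.4 instead of 3.25), Ubb (-1.42 instead of -3.35) and Adgrb2 (-2.07 instead of -3.18).

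The count past the threshold was 7190 of 19122 (37.6%), with 3313 higher and 3877 lower, and 3041 also differed by over 2-fold. The counts within lists below stand beside that share of 37.6%. With 75th percentile scaling the split was 4828 higher and 3053 lower, after a shift of the median of all genes from -0.052 to 0.157, and with the authors' deposited values it was 6964 higher and 2930 lower, after a shift to 0.85. The count was 3080 without ATF6bKO replicate 1 and 3795 without ATF6bKO replicate 2. As bounds, the beta-globin gene Hbb-b2 was at least 6.32-fold lower, Prkag1, an AMP-activated kinase subunit gene, at least 5.98-fold and Endod1 at least 3.40-fold, while Olfr77 was at least 2.27-fold, Ptgdr, a prostaglandin receptor gene, at least 2.15-fold and Dpy19l2 at least 1.99-fold higher. The log2 difference of Hbb-b2 was -1.20 without WT replicate 1 and -4.12 without WT replicate 2, and it did not pass without any 1 of the 4 knockout arrays, with only the 4 arrays compared or with a trended and robust variance, nor did Ptgdr without ATF6bKO replicate 1 or Dpy19l2 without ATF6bKO replicate 2. With the processed signal these 6 genes lay further from WT, from 3.18 for Olfr77 to 3.87 for Ptgdr and from -4.86 for Prkag1 to -4.16 for Endod1.

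By camera, 0 of the 26 lists passed in ATF6bKO against WT, while 6 had an unadjusted p under 0.05. The number depended on single arrays and was 7 without WT replicate 2 and 1 without WT replicate 1 or ATF6bKO replicate 2. Counts adjusted over the list alone were within 2 of those given below. In the cartilage list, 9 of 26 rose and 2 fell, with a median of 0.59 (-0.64 in the authors' deposited table) and an adjusted p of 0.124, or 0.988 as the adjusted p with an estimated correlation; without ATF6bKO replicate 1 the median was 0.19 (adjusted p = 0.41), without ATF6bKO replicate 2 it was 0.97 and the list passed (adjusted p = 0.000193), and without WT replicate 2 the list passed as well (adjusted p = 0.0117). With the processed signal the median was 0.91 and the list did not pass. Of 29 ER chaperones, 4 rose and 3 fell, with Ero1a 3.56-fold and Sdf2l1 2.33-fold higher. Hspa5 had a log2 difference of 0.97 ± 0.68 (SE; limma adjusted p = 0.288), and Xbp1 one of 0.72 ± 0.40 (SE; limma adjusted p = 0.196). Both passed without WT replicate 1, at 1.98 for Hspa5 and 1.12 for Xbp1, while Hspa5 stood at -0.03 without WT replicate 2, at 0.27 without ATF6bKO replicate 1 and at 1.68 without ATF6bKO replicate 2. In the authors' deposited table both passed, at 8.29 and 6.95. Of 53 translocon, coat and glycosylation genes, 7 rose and 8 fell, among them the KDEL receptor gene Kdelr1, 4.12-fold lower, and Cope, 2.25-fold lower. Of 13 ER stress sensors and relatives, 1 rose and 3 fell; Creb3l1 was 3.16-fold lower, and Creb3, well above background on 1 of the 2 ATF6bKO arrays, also 3.16-fold lower. Of 29 PERK and ATF4 stress genes, 1 rose and 9 fell, with the amino acid transporter gene Slc7a5 2.78-fold and Ddit3 2.65-fold lower. Of 17 hypertrophic chondrocyte genes, 3 rose and 3 fell, and of 32 signalling genes, 9 rose and 7 fell. Pth1r, the receptor for parathyroid hormone-related protein, was 6.17-fold lower and Tgm2 2.15-fold lower. Of 9 resting zone genes, 4 fell, with Apoe 2.69-fold and Clu 1.88-fold lower, although Clu did not pass without ATF6bKO replicate 2. Of 27 cell cycle genes, 11 rose and 4 fell, with Birc5 2.89-fold and Mcm2 2.12-fold higher. Collagen modification genes rose in 3 and fell in 6 of 28, with the prolyl hydroxylase gene P3h3 2.39-fold lower. Genes for ER-associated degradation rose in 2 and fell in 4 of 18, with Aup1 2.25-fold lower, and hypoxia and glycolysis genes rose in 5 and fell in 7 of 26. With the mean over probes the log2 difference was -1.17 for Kdelr1 instead of -2.04 and 0.57 for Birc5 instead of 1.53.

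Among markers of other cell types in ATF6bKO, endothelial markers rose in 1 and fell in 6 of 17, with Plvap 3.68-fold lower, and erythroid markers rose in 2 and fell in 5 of 13, with Slc4a1 4.57-fold lower. Osteoblast and osteocyte markers fell in 3 of 12, osteoclast markers rose in 2 and fell in 2 of 14, and macrophage markers rose in 1 and fell in 6 of 15. Neutrophil markers rose in 4 and fell in 3 of 17, B cell markers rose in 3 and fell in 2 of 13, skeletal muscle markers rose in 3 and fell in 5 of 18, adipocyte markers fell in 3 of 14, and perichondrium, tendon and synovium markers rose in 1 and fell in 1 of 13. Ribosomal protein genes rose in 8 and fell in 4 of 29, oxidative phosphorylation genes rose in 7 and fell in 8 of 32, immediate early and heat shock genes rose in 3 and fell in 3 of 20, and interferon response genes rose in 3 and fell in 2 of 18. Median and mean differed in sign for ER chaperones (-0.03 and 0.03), growth plate signalling (-0.08 and 0.03) and neutrophil markers (-0.05 and 0.01), and the camera direction was upward although median and mean were below 0 for the translocon list (-0.01 and -0.07) and the perichondrium list (-0.04 and -0.06).

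The differences of the 2 knockouts from WT ran in parallel. Of the genes past the threshold, 2934 were higher in both and 3428 lower in both, against 673 and 866 for independent lists of the same sizes, and 0 passed in opposite directions. In 100 simulations of unchanged groups that share the WT arrays, at most 2 genes passed in the same direction in both, against 6362 here; neither this value nor that of independent lists holds both real effects and shared arrays. The log2 differences of ATF6aKO and ATF6bKO from WT correlated across genes at r = 0.9314 (genes are not independent replicates). Both comparisons share the WT arrays, and the same simulations gave r from 0.4768 to 0.5278. The covariance was 0.571 against a simulated 0.0270, a difference of 0.544. The simulations gave a gene the same spread on every array. The 2 WT arrays were over 2-fold apart in 4.8% of genes, against 0.894% for ATF6aKO and 0.523% for ATF6bKO. Part of the excess may therefore come from the shared controls, and no comparison used separate WT arrays for the 2 knockouts. The simulations also held no slide or channel effect. The 4 knockout arrays shared a slide and channel that held no WT array. Such a batch effect alone could give parallel differences, so the excess cannot tell it from a genotype effect shared by both knockouts.

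**Figure D2:**
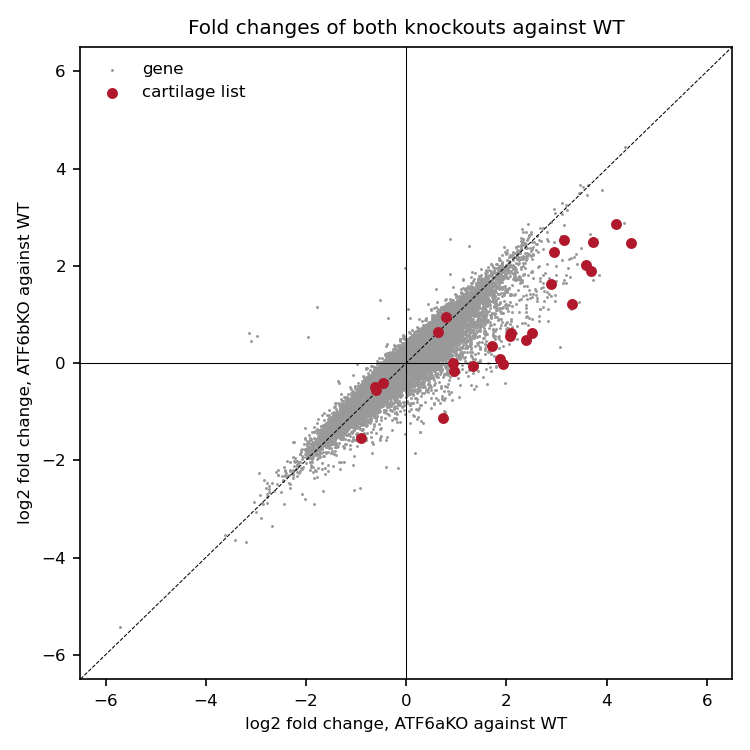
Log2 fold change against WT of ATF6aKO (x axis) and ATF6bKO (y axis) for 19122 genes (grey points) with the cartilage list in red; the dashed line marks equal values. The points follow the line (r = 0.9314), and the 26 cartilage genes have a median of 2.0 on the x axis and 0.59 on the y axis.

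ATF6aKO against ATF6bKO compared the knockouts within 1 slide. No single gene passed over all genes tested, but genes of cartilage and of the secretory pathway stood higher in ATF6aKO as groups with a preset correlation. With an estimated correlation no list passed, at an adjusted p of 0.405 for the cartilage, chaperone and translocon lists. In the cartilage list 21 of 26 members had higher means in ATF6aKO, and 18 of them passed when adjusted over the list alone, against 0 over all genes. The list's median log2 difference was 1.35, with an adjusted p of 8.17e-19 for camera with its preset correlation and an adjusted p of 0.405 with an estimated correlation; without ATF6bKO replicate 2 the median was 0.71. Cnmd, the cartilage protein chondromodulin, measured 13.1 ± 0.37 in ATF6aKO and 11.3 ± 0.23 in ATF6bKO (log2 intensity, SD, n = 2), a difference of 1.79 ± 0.25 (SE; limma adjusted p = 0.611). Matn1 had a log2 difference of 2.03 ± 0.33 (SE; limma adjusted p = 0.611).

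By limma, 0 of 19122 genes passed, while 1169 (6.11%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.611. The count was also 0 under each alternative processing, except that 8 genes, all lower in ATF6aKO, passed without ATF6aKO replicate 2. The genes of smallest p with higher means in ATF6aKO were Rab34 (log2 difference 1.2), Cnmd, Vit (1.53), Capn6 (1.57) and Ecrg4 (1.96), and those with lower means were St6galnac3 (-1.27), Arl4a (-1.06), the vomeronasal receptor genes Vmn1r235 (-0.78) and Vmn2r112 (-0.62), and Rabgef1 (-0.78); none of these passed. The difference between knockouts was 0.06 for Atf6 and 0.11 for Atf6b.

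The 10 lists past the threshold with the preset correlation all had higher values in ATF6aKO, and each lost its call with an estimated correlation (adjusted p from 0.405 to 0.48). With the authors' deposited values 0 lists passed, and 7 of the 10 medians had the opposite sign. The knockout columns there follow the green channel, which the labels do not assign to any RNA. Their differences between the knockouts correlated with those reported here at r = 0.00328, so that table does not test these lists. Of 53 translocon, coat and glycosylation genes, 47 had higher means (median 0.69, list adjusted p = 4.83e-15), and 0 passed when adjusted over the list alone, with Lman1, a cargo receptor gene, at 1.15 and Kdelr1 at 0.81. Of 29 ER chaperones and folding enzymes, 26 had higher means and 3 passed when adjusted over the list alone (median 0.48, list adjusted p = 3.13e-09). Values of Fkbp11, the lectin chaperone gene Canx and Hspa5 were 1.33, 1.34 and 1.67 higher on the log2 scale. Of 29 ribosomal protein genes, 25 had higher means and 6 passed over the list alone (median 0.71, list adjusted p = 6.71e-10), with Rpl32 at 1.35. Oxidative phosphorylation genes had higher means in 28 of 32 (median 0.37, list adjusted p = 1.36e-07), with Atp5o at 0.93. Collagen modification genes did so in 21 of 28 (median 0.37, list adjusted p = 1.67e-05) and genes for ER-associated degradation in 14 of 18 (median 0.32, list adjusted p = 0.000394), with Herpud1 at 1.05. Hypertrophic chondrocyte genes did so in 12 of 17 (median 0.41, list adjusted p = 0.00136), with the sphingomyelinase gene Smpd3 at 1.85 and Pth1r at 0.97. Hypoxia and glycolysis genes did so in 16 of 26 (median 0.22, list adjusted p = 0.00378) and ER stress sensors in 11 of 13 (median 0.11, list adjusted p = 0.0075), with Creb3l2 at 0.74 and Xbp1 at 1.29. Adjusted over the list alone, 1 sensor gene and 1 oxidative phosphorylation gene passed, and 0 of the collagen modification, degradation, hypertrophic and hypoxia genes. Without ATF6bKO replicate 2, the sensor, hypertrophic and hypoxia lists no longer passed (adjusted p = 0.0743, 0.101 and 0.24), nor did the sensor list without ATF6aKO replicate 1 (adjusted p = 0.355) or with probes well above background on all 6 arrays (median 0.06, adjusted p = 0.114). Single arrays also moved medians. Without ATF6aKO replicate 2 they were 0.44 for the translocon list, 0.23 for collagen modification, 0.20 for oxidative phosphorylation and 0.23 for the sensors. Without ATF6bKO replicate 2 they were 0.18 for ER-associated degradation, 0.18 for collagen modification, 0.195 for hypertrophic genes and 0.076 for hypoxia and glycolysis. Without ATF6bKO replicate 1 they were 0.64 for collagen modification and 0.28 for the sensors, and without ATF6aKO replicate 1 the sensor median was 0.015. Smpd3 differed by 2.49 without ATF6bKO replicate 1 and by 1.22 without replicate 2, and Hspa5 by 2.37 and 0.965. With the processed signal the medians were larger for the sensor list (0.22), collagen modification (0.58) and hypoxia and glycolysis (0.325). The hypoxia and glycolysis median was 0.14 with 75th percentile scaling.

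The PERK and ATF4 stress, resting zone, growth plate signalling and cell cycle lists did not pass between the knockouts (medians 0.04, -0.04, 0.06 and -0.03; unadjusted camera p from 0.22 to 0.639). No list of another cell type passed, with medians from -0.13 for neutrophil markers to 0.08 for osteoblast and osteocyte markers, nor did the immediate early and heat shock or interferon response lists (medians -0.02 and 0.04). The median and the direction of the test differed for osteoblast and osteocyte, B cell, perichondrium, immediate early and heat shock, and interferon response genes. Per array, the median deviation of the cartilage list from the mean over the 6 arrays was 0.88 and 1.19 in ATF6aKO, 0.21 and -0.65 in ATF6bKO, and -0.90 and -0.68 in WT. Between the 2 ATF6bKO arrays the median difference of this list's genes was 0.755.

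**Figure D3:**
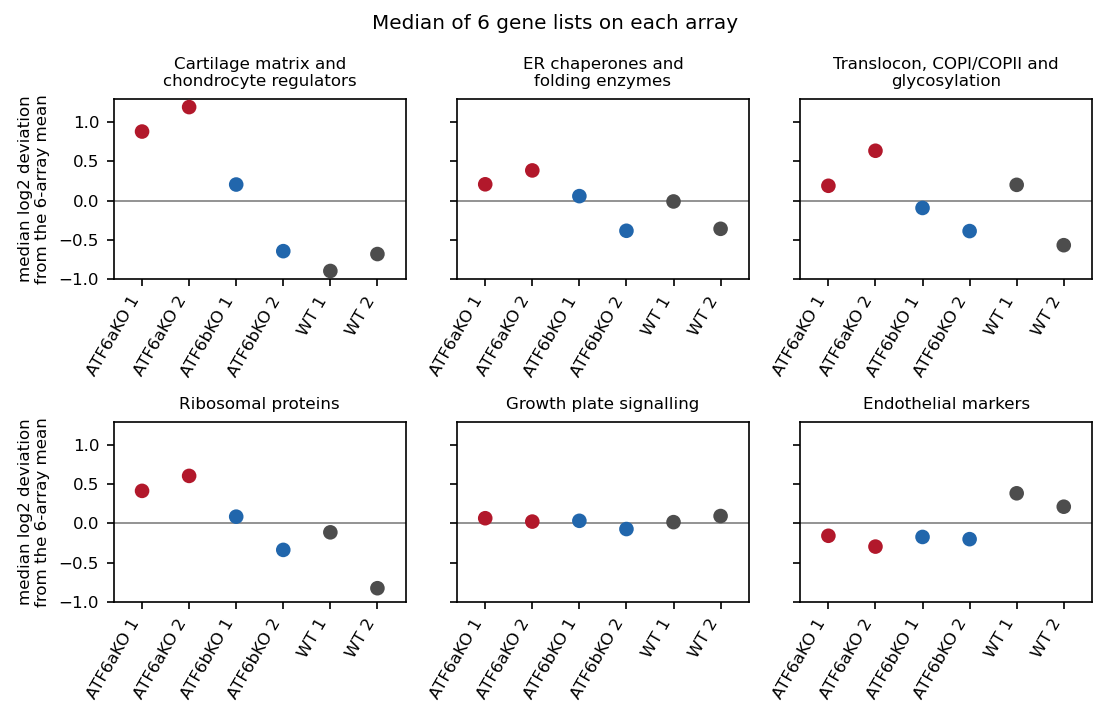
Median deviation of each list's genes from their mean over the 6 arrays (y axis, log2 units) on each array (x axis), coloured by genotype, with the arrays of a genotype side by side. For the cartilage list the ATF6aKO arrays stood at 0.88 and 1.19 and the ATF6bKO arrays at 0.21 and -0.65, whereas growth plate signalling stayed between -0.07 and 0.09 on all 6 arrays.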

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

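The tests of the slide and row, of the deposited table, of probe pairs, of the tissue share and of the axis between arrays were chosen after the results were seen; the share of chemosensory receptor genes was predicted before it was computed, although 4 such receptor genes had already appeared among the named genes.

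The green channel of the knockout arrays, which the labels do not assign to any RNA, carried signal in data that the comparisons did not use. Non-control spots well above background in it made up 11.4% and 9.59% in ATF6aKO and 12.5% and 8.45% in ATF6bKO, against 0.325% to 0.974% of negative control spots. Across probes its log2 signal correlated with the red channel at r = 0.339 to 0.425. The deposited knockout values followed this channel, since differences between ATF6aKO replicate 1 and ATF6bKO replicate 1 in the deposited table correlated with the green signal at r = 0.9989 and with the red signal at r = 0.0392. No biological explanation was tested for this, and it is consistent with the deposited knockout values having been taken from the green channel. Under that table the log2 differences from WT correlated with those reported at r = 0.36 for ATF6aKO and 0.229 for ATF6bKO, and those between the knockouts at r = 0.00328.

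Between ATF6aKO and WT 8157 genes differed, and 7190 between ATF6bKO and WT. A channel, slide or scan effect that depends on the probe may account for part of them. Among 1274 olfactory and vomeronasal receptor genes, best known from sensory neurons, 39.9% passed in ATF6aKO against WT, against 42.9% of other genes. In ATF6bKO against WT 37.8% of these receptor genes passed, against 37.6% of other genes. The log2 differences of 2 probes of a gene differed with an SD 3.03 times what the replicates allow, against 0.95 times between the knockouts. A lower share of chondrocytes in the WT captures stays open too: markers of other cell types moved apart over 144 genes (permutation p = 0.0376 for ATF6aKO and 0.0099 for ATF6bKO), but not detectably without WT replicate 1 (permutation p = 0.446 and 0.516), so that array decides the test. A genotype effect shared by both knockouts stays open and cannot be told apart from the batch, since 0 slides held WT and knockout arrays.

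With a preset correlation, cartilage, secretory and ribosomal lists were higher in ATF6aKO than in ATF6bKO, but 0 of 19122 genes passed, and no list passed with an estimated correlation (camera adjusted p = 0.405 for each of these lists). An axis that also separates arrays of 1 genotype may contribute, because across genes the difference between knockouts correlated at r = 0.394 with ATF6bKO replicate 1 minus replicate 2, beyond the -0.0389 to 0.0352 of simulated unchanged groups, at r = 0.211 with ATF6aKO replicate 2 minus replicate 1 and at r = 0.323 with WT replicate 1 minus replicate 2. In that order, the medians along these axes were 0.76, 0.29 and -0.28 for the cartilage list, 0.27, 0.37 and 0.68 for the translocon list and 0.30, 0.21 and 0.75 for ribosomal proteins, so the cartilage list ran the other way between the WT arrays. The difference between knockouts holds the knockout arrays themselves, and the simulations gave every array the same spread. A noisier array could therefore raise the r with a knockout axis, so those values cannot settle whether such an axis exists. The WT arrays are not part of that difference. The sign of each r depends on which array of the pair comes first. The position of the arrays on the slide cannot be told apart from genotype here, since 0 slide rows held both knockouts. A difference between the genotypes also stays open.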

How the results depend on the processing

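Testing all features, matched to a gene or not, the crossed replicate block and the permutation test with each WT array alone were chosen after the data were examined; the other alternatives were chosen before. Of the alternative values for the 115 results on single genes, 1734 kept the direction and side of the threshold. Another 44 were no longer past it, 8 were newly past it and 40 had the opposite sign. For 16 lists these numbers were 222, 39, 2 and 9. The authors' deposited table, whose knockout columns follow the green channel, alone gave 33 of the 40 opposite signs and 20 of the 44 lost calls. Every list median with the opposite sign also came from that table. The slide as a block was not run, because WT lay alone on its slide and the knockouts shared theirs. Signal over background limits the dim probes, since the median signal was 146 to 183 over a background of 37 on the knockout arrays.

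The count of genes past the threshold was 3593 for ATF6aKO and 3041 for ATF6bKO against WT when a log2 difference over 1 was also required, and 15861 and 14236 of 35393 features when unmatched probes were kept, which tests more features. With an estimated correlation 0 lists passed in ATF6aKO against WT and 0 between the knockouts. In ATF6aKO against WT 2 lists passed with probes well above background on all 6 arrays and 1 with 75th percentile scaling. That scaling gave Atf6 differences of 0.075 for ATF6aKO and 0.076 for ATF6bKO against WT and -0.001 between the knockouts; the cause was not tested.

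The authors' deposited values, whose knockout columns follow the green channel, gave 8 lists in ATF6bKO against WT, 0 between the knockouts, and a correlation of 0.9547 between the differences of the knockouts from WT. The cartilage list had medians of -0.407 in ATF6aKO and -0.64 in ATF6bKO against WT. In ATF6aKO against WT the opposite sign was found for Atf6 (0.95), Col10a1 (-1.184), Col2a1 (-0.45), Cdkn1c (-0.8), Eef2 (1.993), Myo10 (0.4), Cope (0.1), Ddit3 (3.25), Barx1 (0.15), Kdr (0.826), Lyz2 (-0.45) and Col1a2 (3.0). In ATF6bKO against WT it was found for Atf6 (2.522), Olfr1386 (-0.6), Fbxw7 (-0.35), Eef2 (2.277), Ubb (2.85), Prkag1 (0.6), Col2a1 (-0.95), Matn1 (-0.47), Cope (0.15), Creb3 (2.15) and Ddit3 (3.75), while Atf6b (-2.15), Hspa5 (8.285) and Xbp1 (6.95) newly passed. Calls also ended, with the sign kept, for Matn1 (0.001), H2-Q2, Trp53i11, Trp53rkb, Ero1a, Ihh, Tgm2, P3h4, Pfkl and Tnni2 in ATF6aKO, and for D7Ertd143e, Smim13, Rmrp, Hbb-b2, Endod1, Ero1a, Kdelr1, Clu, P3h3 and Aup1 in ATF6bKO. Between the knockouts it was found for Atf6 (-1.572), Hspa5 (-0.106), Xbp1 (-0.25), Capn6 (-0.15), Arl4a (0.05), Canx (-0.15), Kdelr1 (-0.35), Herpud1 (-0.15), Rpl32 (-0.098) and Atp5o (-0.25), and for the medians of ER chaperones (-0.2), ER-associated degradation (-0.125), translocon and coats (-0.1), collagen modification (-0.15), hypoxia and glycolysis (-0.116), ribosomal proteins (-0.093) and oxidative phosphorylation (-0.075). The cause of these was not tested gene by gene.

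Leaving out each array in turn gave 4682 to 8061 genes and 2 to 5 lists in ATF6aKO against WT, 3080 to 7019 genes and 0 to 7 lists in ATF6bKO against WT, and 0 to 8 genes and 7 to 10 lists between the knockouts. The Atf6 difference of ATF6aKO from WT ranged from -0.264 to -0.028, the Atf6b difference of ATF6bKO from WT from -0.718 to -0.359 and the correlation from 0.8888 to 0.9456. The sign turned for Atf6b between the knockouts without ATF6aKO replicate 1 or ATF6bKO replicate 2 (-0.071), with a range of -0.112 to 0.33, for Col1a2 in ATF6aKO against WT without WT replicate 1, with a range of -4.748 to 2.647, and for Hspa5 in ATF6bKO against WT without WT replicate 2, with a range of -0.026 to 1.976.

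Arrays with the same replicate number did not deviate together in every pair of genotypes (r across genes -0.156 between the knockouts, -0.0743 for ATF6aKO and WT, 0.197 for ATF6bKO and WT), so they share only a number. With the replicate block 7594 genes passed in ATF6aKO and 6630 in ATF6bKO against WT and 0 between the knockouts, with 5, 0 and 10 lists. The crossed block gave 8652, 7710 and 0 genes, again with 5, 0 and 10 lists.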

Other observations

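Of the 1322 olfactory and vomeronasal receptor genes on the array, 1274 passed the filter on dim probes. These counts were chosen after the differences between the genotypes were seen. In ATF6aKO against WT, 362 of them were higher and 146 lower, and in ATF6bKO against WT 359 were higher and 122 lower. The 2 WT arrays were over 2-fold apart in 4.8% of genes, against 0.894% for the ATF6aKO arrays and 0.523% for the ATF6bKO arrays.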
